A study of Bradyrhizobium diazoefficiens USDA 110 with 18 samples.

How the data were processed

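Bacterial cells grown in minimal medium with yeast extract and glycerol were filtered at mid-log phase and kept at 27% or 100% relative humidity for 4, 24 or 72 h, per the labels. Total RNA was extracted with hot phenol, copied to cDNA with random hexamers and labelled with cy3 or cy5, per the labels' protocols. Each of the 18 arrays compared desiccated with hydrated cells of one time. Odd replicate numbers had the desiccated cells in cy3 and even ones in cy5, per the labels. Nothing in the labels says that arrays came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

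The authors deposited 1 table of log ratios per probe and array, taken here as likely log10 ratios, for 8480 probes on 18 arrays, with 0 missing values and 0 values of exactly 0. The scanner, the background correction, the normalization and the averaging of spots are not given in the sources used here. Each array's mean lay near 0, and array medians ranged from −0.0048 to 0.0084 at 4 h, from −0.0126 to 0.0046 at 24 h and from −0.0273 to −0.0085 at 72 h, so the deposited values lay near 0 on each array before any step taken here. The log base stays unknown. Base 10 was taken as likely because the spread of the difference between partner arrays (SD 0.037 to 0.133) would be a noise per array of 1.8% to 6.8% in base 2, low for spotted arrays, and of 6.1% to 24.3% in base 10. The design was written for log2 ratios; the tests are the same on either base, and folds are given in both. The direction stays unknown as well. Desiccated over hydrated was taken as likely because the titles name desiccation first and arrays of opposite dye correlated positively (mean r across genes 0.50, 0.58 and 0.59 at 4, 24 and 72 h), as they would not if the ratios were one dye over the other.

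Probes were named through an annotation of the array platform, which can be old. Of 8480 probes, 8462 were listed there and 18 were not; 1469 had 1 gene symbol, 0 had several and 7011 had a locus tag only. Locus tags were taken from the probe names. Probes of one tag were averaged, giving 8268 genes, 192 of them with several probes. Different probes of a gene gave changes that correlated little (r = 0.21, 0.17 and 0.20 over 212 probe pairs at 4, 24 and 72 h), so the probe carrying the plain tag was tried alone. A newer gene table could not be matched to these tags and was not used. No product descriptions were used, so list patterns on products took no genes: 3 of the 37 lists, which rested on them, held 0 measured genes.

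All tests used limma 3.58.1 and statmod 1.5.0 in R 4.3.3. One model per gene over all 18 arrays had a mean for each time and a dye term, lmFit and eBayes gave 2-sided moderated tests of each time's mean against 0 and of the differences between times, and p-values were adjusted by Benjamini-Hochberg over 8268 genes. An adjusted p under 0.05 was called. The dye term was called for 0 genes (24 at an unadjusted p under 0.05, limma). With no dye effect at all, a share of about 0.05 of the 8268 genes would lie under that threshold, far more than 24. The test was thus too strict to show that dye had no effect. The same tests were run on 9 means of presumed dye-swap pairs, without the dye term. Partner arrays had residuals that correlated with 0.55 (duplicateCorrelation), so the test over 18 arrays may count one pair of RNA samples as 2 replicates. On simulated data for the 24 h comparison of 8268 genes, with 100 genes changed by 0.15 and 100 by 0.3, the 18-array test recovered 79 and 97 with 8 false calls when noise was independent, and 82 and 99 with 92 false calls when partner arrays shared noise. The pair means recovered 75 and 97 with 10 false calls, and 53 and 96 with 5.

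The 37 gene lists were fixed before the data were examined, as locus tags and patterns on symbols. They held 612 genes, 20 of them in over 1 list. The list of translation factors and tRNA synthetases took in unrelated genes through its pattern (nifS and pstS, for example) and was not described; it had 6 higher and 4 lower of 51 at 24 h, and 5 and 6 at 72 h (8 and 2 with arrays centred, 7 and 2 also scaled). The 32 lists with at least 4 measured genes were tested at each time (96 tests, Benjamini-Hochberg) with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether a list moves one way on balance and compares it with no other genes. Camera called 6 of 96 at the preset correlation and 0 at an estimated one, and fry called 40.

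Genes were named by a rule fixed before the data were examined. For each time these were the 10 largest increases and decreases among called genes with the same sign on 6 of 6 arrays and a symbol, for each difference between times the 5 largest each way, and up to 4 members of a described list with the smallest adjusted p. Members of the trehalose, glyoxylate and sigma factor lists could be named at any p. Since most genes have only a tag, up to 2 higher and 2 lower tags per time were named after their values were seen.

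Alternatives were no dye term, arrays centred or also scaled, each time fitted alone, array weights, robust eBayes, the replicate number as a block, presumed pairs averaged or as a random block, a 2-fold minimum, one dye orientation alone, and each array left out in turn. Added after the data were examined were the plain-tag probe, leaving out 2 partner arrays together, pair means without 4 h arrays 5 and 6, and pairs in the overlap of times. A filter to genes measured on all 18 arrays removed 0 genes and was not run further.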

Results

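*Bradyrhizobium diazoefficiens* USDA 110, called *B. japonicum* in the study's title, is a soil bacterium that forms nodules on soybean and fixes nitrogen in them. Growing cells were collected on membranes and kept for 4, 24 or 72 h in air of 27% relative humidity (desiccated cells) or 100% relative humidity (hydrated cells), and transcript levels were compared to learn which genes respond to drying. Each 2-colour array held cDNA from desiccated and hydrated cells of one time. There were 18 arrays, 6 for each time, with the desiccated cells in cy3 on 3 arrays and in cy5 on 3 arrays of each time. The 8480 probes stood for 8268 genes, of which 1446 had a gene symbol and 6822 only a locus tag, and every probe had a value on every array. The number of arrays limits the precision of each mean.

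Values are mean log ratios of desiccated over hydrated cells ± SD over the 6 arrays of a time. The log base and the direction were not given in the sources used here. Base 10 and desiccated over hydrated were taken as likely, and every "higher" and "lower" rests on that direction. A value of 0.30 would be 2.00-fold in base 10 and 1.23-fold in base 2. Arrays 1 and 2, 3 and 4, and 5 and 6 of a time carried opposite dyes and were on average more alike than other arrays of the time. Their mean correlation across genes was 0.77 at 4 h, 0.88 at 24 h and 0.71 at 72 h, against 0.38, 0.42 and 0.53 for the other arrays. This was least clear at 72 h, where arrays 1 and 2 correlated at 0.50, and array 1 more with arrays 5 (0.74), 6 (0.72) and 3 (0.53). At 4 h arrays 5 and 6 correlated at 0.57, below some arrays of different pairs (up to 0.79). They were treated as presumed dye-swap pairs, which the labels do not state, and every gene was tested over 18 arrays and again over 9 pair means. Adjusted p values are given in that order. A gene is said to have risen or fallen only where both were under 0.05, and is otherwise given with its values.

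After 4 h, a gene for making trehalose, a sugar that protects dry cells, had the highest mean among the genes with a symbol that passed over 18 arrays, and no gene passed in both tests. This gene, otsA (bll0322), which encodes trehalose-6-phosphate synthase, stood at 0.32 ± 0.13 (SD, n = 6), which is 2.10-fold in base 10 and 1.25-fold in base 2. It was higher on 6 of 6 arrays (adjusted p = 0.00212 over 18 arrays and 0.266 over pair means). The gene otsB (bll0323), the phosphatase that completes trehalose synthesis, stood at 0.18 ± 0.15 (adjusted p = 0.063 and 0.49). On arrays 5 and 6 otsB stood at 0.017 and −0.019. Both genes passed in both tests when adjusted over the list alone, which holds only these 2 genes. Other genes with higher means on 6 of 6 arrays were glgA (blr6459), glycogen synthase, at 0.21 ± 0.12, rpoN2 (blr0723), a sigma-54 factor of RNA polymerase, at 0.17 ± 0.06, and aglA (blr0901), an alpha-glucosidase, at 0.11 ± 0.06. Means below 0 on 6 of 6 arrays were found for dapD (blr8104), of lysine and cell wall synthesis, at −0.20 ± 0.12, and nrdB (bll0006), a subunit of ribonucleotide reductase, at −0.20 ± 0.16. The same held for dnaA (bll0830), the initiator of chromosome replication, at −0.13 ± 0.08, and dctA (blr4298), the dicarboxylate transporter, at −0.13 ± 0.07. These genes had adjusted p values from 0.01 to 0.047 over 18 arrays and 0.49 over pair means. Of the genes with only a locus tag, chosen after their values were seen, bll0333 stood at 0.47 ± 0.13 (adjusted p = 0.0021 and 0.27).

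Of 8 measured cold shock genes at 4 h, 1 passed over 18 arrays, cspA (bsl1445) at −0.17 ± 0.14, and 0 over pair means; 3 of 8 passed adjusted over the list alone. The list as a whole was lower than other genes, with a median of −0.09 (camera, adjusted p = 0.027 with the preset correlation; adjusted p = 0.51 with an estimated correlation). Of 11 genes for sigma factors and the general stress response, 1 passed, rpoN2, and 3 passed adjusted over the list alone. The flagellar list had 2 higher and 2 lower genes of 55, with flgC (bll5813) at −0.11 ± 0.04 and flgH (blr5830) at 0.09 ± 0.06, and 4 passed adjusted over the list alone. Of 52 ribosomal protein genes, 0 passed over all genes and 5 adjusted over the list alone. With arrays centred and scaled these 4 lists had more calls at 4 h, with 5 cold shock genes lower, 5 sigma factor genes higher, 8 flagellar genes higher and 6 lower, and 6 ribosomal protein genes higher and 4 lower.

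In all, 239 of 8268 genes (2.9%) were called at 4 h over 18 arrays with limma, 100 higher and 139 lower, a balance that turned in several alternatives (5 and 1 without array 1, 2686 and 2242 with array weights). That 4 h had fewer calls than 24 h depended on the setting too. With each time fitted alone 4 h gave 1000 genes and 24 h 891, and with array weights 4928 and 2447. Both settings count partner arrays as separate, and 4 h arrays 3 and 4 were weighted 8.9 and 8.1. With the presumed pairs, 4 h stayed below 24 h. As a random block they gave 4 genes against 1606, and averaged 0 against 974. At 4 h over pair means, 794 genes had an unadjusted p under 0.05 and the lowest adjusted p was 0.27 (limma). Single arrays decided much of the count: it was 6 without array 1, 15 without array 2, 36 without array 3, 16 without array 4 and 428 without array 6, and 710 without arrays 5 and 6 together.

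**Figure D1:**
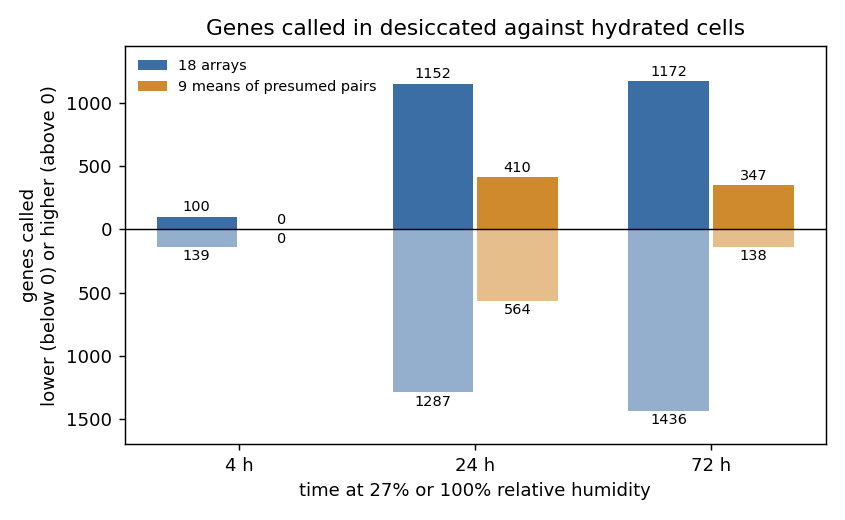
Number of genes called higher (above 0) and lower (below 0) in desiccated cells at each time, from the test over 18 arrays (blue) and over 9 means of presumed pairs (orange). Over pair means 0 genes were called at 4 h, 974 at 24 h and 485 at 72 h.

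After 24 h, both listed genes for trehalose synthesis, 14 of 52 genes for ribosomal proteins and the gene for a subunit of ATP synthase had risen in both tests. Genes that had fallen included rocD, of ornithine breakdown, 3 of 8 for cold shock proteins, ftsH, of a membrane protease, and 2 for methionine sulfoxide reductase. otsA stood at 0.47 ± 0.12 (SD, n = 6), 2.97-fold in base 10 and 1.39-fold in base 2. It was higher on 6 of 6 arrays (adjusted p = 3.31e-07 and 0.00096). Similar increases were measured for glnK (blr0612), a PII signalling protein of nitrogen control, at 0.47 ± 0.22, rpoN2 at 0.45 ± 0.11 and panD (blr2096), of pantothenate synthesis, at 0.43 ± 0.17. The gene for the beta subunit of ATP synthase, atpD (bll0440), rose to 0.41 ± 0.01. Genes that rose by 0.34 to 0.38 were ptsN (blr0725), of the nitrogen-related phosphotransferase system, the DEAD-box RNA helicase gene rhlE (bll1447), ppdK (blr2538), pyruvate phosphate dikinase, and dxs (bll2651), of isoprenoid synthesis.

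The strongest decrease among genes with a symbol was that of rocD (bll2855), ornithine aminotransferase, at −0.48 ± 0.10, 3.01-fold lower in base 10 and 1.39-fold in base 2. It was lower on 6 of 6 arrays (adjusted p = 5.73e-08 and 0.000261). The regulatory gene fixK (bll2757), which acts under low oxygen, fell to −0.46 ± 0.22 and 2 cold shock genes named cspA to −0.44 ± 0.25 (bsr7468) and −0.42 ± 0.12 (bsl1445). Genes that fell to means from −0.42 to −0.40 were tatA (bsl4751), of protein export, cvpA (bll4061), cisZ (bll0182), metX (blr1399), of methionine synthesis, the protease gene ftsH (bll7146) and accD (blr0747), a subunit of acetyl-CoA carboxylase. These had adjusted p values of at most 1.33e-05 over 18 arrays and 0.00535 over pair means. Of the genes with only a locus tag, chosen after their values were seen, bll7487 rose to 0.67 ± 0.11 and blr2455 to 0.89 ± 0.37, and bll4833 and blr0366 fell to −0.76 ± 0.10 and −0.67 ± 0.08.

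The counts of called list members below are to be set against the 29.5% of all genes called at 24 h over 18 arrays. Both listed trehalose genes rose at 24 h, in both tests and adjusted over the list alone, with otsB at 0.25 ± 0.14 (adjusted p = 0.0021 and 0.048). In the list of stores, 3 of 11 genes were higher and 1 lower over 18 arrays (2 and 0 with arrays centred and scaled), 4 adjusted over the list alone and 1 over pair means, which was glgX (blr6769), a glycogen debranching enzyme, at 0.19 ± 0.08. Of 11 sigma factor and general stress genes, 5 were higher and 1 lower (3 and 1 with arrays centred and scaled), 6 adjusted over the list alone. The 3 that passed in both tests were rpoN2 and the locus tags bll7795 (0.30 ± 0.04) and blr7797 (0.11 ± 0.02), which entered the list before the data were examined and for which no gene name was used here. Of 4 genes of the glyoxylate cycle and gluconeogenesis, 2 were higher over 18 arrays and 3 adjusted over the list alone. The gene pckA (bll8141), phosphoenolpyruvate carboxykinase, rose in both tests, to 0.14 ± 0.04. The malate synthase gene glcB (bll1474) stood at 0.08 ± 0.06 (adjusted p = 0.017 and 0.15).

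Ribosomal protein genes were the list with the most members higher at 24 h. Of 52 genes, 27 were higher and 3 lower over 18 arrays, 14 higher and 1 lower over pair means, and 32 passed adjusted over the list alone. The gene rplM (bll4963) rose to 0.30 ± 0.10, rplE (bll5388) to 0.21 ± 0.06, rplO (bll5381) to 0.19 ± 0.05 and rpmB (blr0162) to 0.13 ± 0.05. The list median was 0.09 (camera, adjusted p = 7.35e-06 with the preset correlation; adjusted p = 0.41 with an estimated correlation). In the ATP synthase list 2 of 8 genes were higher over 18 arrays and 2 adjusted over the list alone, and atpD alone rose in both tests. Near it in tag number, atpA (bll0442) stood at 0.10 ± 0.09 (adjusted p = 0.068 and 0.12). The NADH dehydrogenase genes called went both ways, with 5 higher and 4 lower of 13, 10 adjusted over the list alone. Thus nuoH (bll4910) rose to 0.14 ± 0.08, and nuoA (bll4919) and nuoE (bll3138) fell to −0.25 ± 0.09 and −0.27 ± 0.13. Of 34 genes for cytochromes and their oxidases, 10 were higher and 3 lower over 18 arrays, 13 adjusted over the list alone. The gene cycA (blr7544), a soluble cytochrome c, rose to 0.33 ± 0.06. Of the high-affinity cbb3 oxidase, fixP (blr2766) and fixQ (bsr2765) rose to 0.19 ± 0.05 and 0.27 ± 0.06, and coxB (blr1170), of an aa3-type oxidase, fell to −0.33 ± 0.13.

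Several stress lists had more lower than higher members at 24 h. Of 8 cold shock genes, 1 was higher and 5 lower, 6 adjusted over the list alone, and 3 cspA genes fell in both tests, the third being bsl2120 at −0.19 ± 0.08. Of 10 genes for oxidative stress defence, 1 was higher and 5 lower, 6 adjusted over the list alone. The methionine sulfoxide reductase genes msrA (blr7043) and msrA (blr0834) fell to −0.36 ± 0.07 and −0.20 ± 0.06, and thioredoxin reductase, trxB (blr7381), to −0.15 ± 0.04. The superoxide dismutase gene sodF (bll7774) rose to 0.24 ± 0.03 (adjusted p = 1.3e-06 and 0.0025). Of 12 protease genes, 1 was higher and 6 lower, 7 adjusted over the list alone. Besides ftsH, clpS (bll5154) fell to −0.11 ± 0.03 and clpX (bll4943) to −0.19 ± 0.12. The chaperone list shares several genes with the protease list, clpS and clpX among them, so the counts of the lists overlap. Its 35 genes moved both ways, 11 higher and 10 lower, 21 adjusted over the list alone. Of these, htpG (bll7789) rose to 0.19 ± 0.05, while dnaK (blr0678), the Hsp70 chaperone, and the small heat shock genes hspH (blr6571) and hspH (bll0729) fell to −0.32 ± 0.16, −0.37 ± 0.21 and −0.25 ± 0.08. Of 29 genes in the DNA repair list, 5 were higher and 7 lower, 12 adjusted over the list alone. Here uvrA (blr8051), of excision repair, rose to 0.20 ± 0.12 and lexA (blr4826), the SOS repressor, fell to −0.30 ± 0.11. The list also took in mutA (bll3054), a symbol used for a subunit of methylmalonyl-CoA mutase as well, which fell to −0.34 ± 0.07. None of these 5 lists passed camera at 24 h.

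Of genes of movement, those called were mostly higher at 24 h, and most were not called. Of 14 chemotaxis genes, 6 were higher and 0 lower over 18 arrays, 7 adjusted over the list alone and 1 over pair means. The list median was 0.07 (camera, adjusted p = 0.017; adjusted p = 0.34 with an estimated correlation). The response regulator gene cheY (blr2194) rose to 0.33 ± 0.27 on 5 of 6 arrays (adjusted p = 0.0011 and 0.032, and 0.064 with 24 h fitted alone). The methylesterase gene cheB (blr2195) stood at 0.12 ± 0.06 (adjusted p = 0.0023 and 0.054). The flagellar list had 13 higher and 2 lower of 55, 15 adjusted over the list alone and 8 higher over pair means. Its called share was near the 29.5% of all genes. The gene fliN (blr7002), of the flagellar switch, rose to 0.20 ± 0.11 and flhA (bll2207), of flagellar export, to 0.13 ± 0.05.

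Among genes of nutrient supply, 9 of 37 for phosphate and nitrogen starvation were higher and 2 lower, 11 adjusted over the list alone. This called share was near the 29.5% of all genes. Besides glnK, the ammonium transporter gene amtB (blr0613) rose to 0.19 ± 0.07 and phoC (bll7947) fell to −0.10 ± 0.03. Of 11 iron genes, 0 were higher and 4 lower (0 and 2 with arrays centred and scaled), 4 adjusted over the list alone. The iron response regulator gene irr (bll0768) fell to −0.35 ± 0.07 and the regulator gene fur (bll0797) stood at −0.13 ± 0.12 (adjusted p = 0.0039 and 0.061). Exopolysaccharide genes had 4 higher and 1 lower of 10, 5 adjusted over the list alone, with exoN (blr1499) at 0.24 ± 0.08 and pssA (blr3797) at −0.30 ± 0.15. Few genes of 2 symbiosis lists were called: 1 of 33 nodulation genes and 1 of 10 type III secretion genes were higher over 18 arrays. Both lists had 1 gene adjusted over the list alone and 0 over pair means. Of 22 nitrogen fixation genes 4 were higher and 2 lower, a share near that of all genes, and 6 passed adjusted over the list alone. Here fixX (bsr1775) and nifZ (blr1761) rose to 0.17 ± 0.07 and 0.11 ± 0.06.

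In all, 2439 genes (29.5%) were called at 24 h over 18 arrays, 1152 higher and 1287 lower (1247 and 1202 with arrays centred, 1076 and 1004 also scaled), of which 1589 had the same sign on 6 of 6 arrays. Over pair means 974 were called, 410 higher and 564 lower, all within the former. The count was 891 with 24 h fitted alone and 1354 without arrays 3 and 4, and 211 genes reached 2-fold in base 10.

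**Figure D2:**
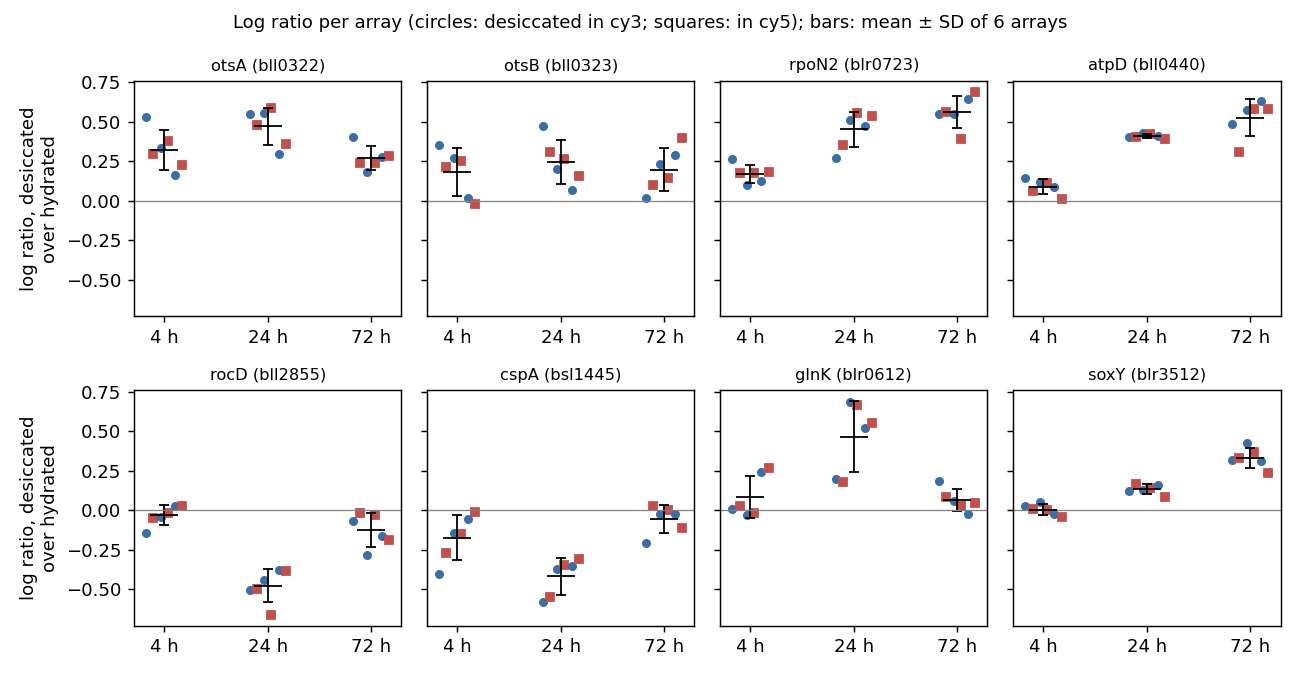
Log ratio, desiccated over hydrated, of 8 genes on each array at 4, 24 and 72 h (circles, desiccated cells in cy3; squares, in cy5), with the mean ± SD of 6 arrays as bars. otsA lies above 0 on all arrays of the 3 times, rocD is lowest at 24 h (mean −0.48) and soxY is highest at 72 h (mean 0.33).

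After 72 h, rpoN2 and atpD stood highest among the genes with a symbol, together with 2 pilus genes named ctpA. The mean of rpoN2 reached 0.56 ± 0.10 (SD, n = 6), 3.66-fold in base 10 and 1.48-fold in base 2 (adjusted p = 1.22e-08 and 0.00053), and atpD 0.53 ± 0.12 (adjusted p = 1.93e-09 and 0.000394), both higher on 6 of 6 arrays. The pilus genes ctpA (bsl7141) and ctpA (bsl1442) rose to 0.56 ± 0.19 and 0.50 ± 0.15. Among other genes higher on 6 of 6 arrays, metF (bll1419), of methionine and folate metabolism, rose to 0.40 ± 0.11, and rnpO (bll5066), to 0.39 ± 0.09. There were also pqqA (bsr6735), the precursor of the cofactor PQQ, which rose to 0.35 ± 0.17, and soxY (blr3512), of sulfur oxidation, which rose to 0.33 ± 0.06. Genes that fell in both tests included lysA (blr1383), the last enzyme of lysine synthesis, to −0.20 ± 0.03 (adjusted p = 2.12e-05 and 0.0127), and phnG (blr1221), of phosphonate use, to −0.18 ± 0.06. So did lpxA (bll4849), of lipid A synthesis, at −0.18 ± 0.10, hyfB (blr6339), a hydrogenase component, at −0.18 ± 0.04, and the export chaperone gene secB (bll0641) at −0.16 ± 0.07. The mean of fixK stood at −0.44 ± 0.29 (adjusted p = 0.00134 and 0.0567). Of the genes with only a locus tag, chosen after their values were seen, bll5191 rose to 0.66 ± 0.19 and bll5085 to 0.63 ± 0.19, and bll4833 and blr7331 fell to −0.53 ± 0.21 and −0.42 ± 0.11.

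Of the trehalose genes, otsA was still higher at 72 h, at 0.27 ± 0.08 (adjusted p = 0.000192 and 0.0203). The mean of otsB was 0.20 ± 0.14 (adjusted p = 0.011 and 0.11, and 0.058 without array 6). Both passed in both tests adjusted over the list alone, which holds only these 2 genes. List counts at 72 h are to be set against the 31.5% of all genes called over 18 arrays. Of 11 sigma factor and general stress genes, 5 were higher and 2 lower over 18 arrays and 7 adjusted over the list alone. Again rpoN2, bll7795 (0.40 ± 0.11) and blr7797 (0.19 ± 0.09) rose in both tests, and rpoH2 (blr7337), a heat shock sigma factor, stood at 0.17 ± 0.12 (adjusted p = 0.002 and 0.061). Ribosomal protein genes had 13 higher and 1 lower of 52 (20 and 0 with arrays centred, or also scaled), 3 higher over pair means and 11 adjusted over the list alone (camera, adjusted p = 0.000595; adjusted p = 0.51 with an estimated correlation). Here rplO, rplP (bll5393) and rplM rose to 0.28 ± 0.05, 0.26 ± 0.09 and 0.23 ± 0.05. In the chaperone list 12 of 35 genes were higher and 1 lower over 18 arrays, 14 adjusted over the list alone and 0 over pair means. The mean of groES (blr6978) was 0.20 ± 0.12 (adjusted p = 0.0018 and 0.06). That of clpP (bll4944), which is in the protease list as well, was 0.16 ± 0.01 (adjusted p = 0.0024 and 0.071). The median of the chaperone list was 0.04 (camera, adjusted p = 0.017, and adjusted p = 0.45 with an estimated correlation).

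Of 17 genes in the pilus list, 7 were higher and 1 lower at 72 h, 9 adjusted over the list alone and 2 over pair means, which were the ctpA genes given above. The list median was 0.06 (camera, adjusted p = 0.032; adjusted p = 0.51 with an estimated correlation). The list was drawn up by symbol and includes ctpA (bll4822), at 0.15 ± 0.04, which may not be a pilus gene. In fatty acid synthesis 6 of 23 genes were higher and 2 lower (6 and 0 with arrays centred), 8 adjusted over the list alone. The enoyl-ACP reductase gene fabI (blr3459) rose to 0.45 ± 0.28, fabF (bll2529), a ketoacyl-ACP synthase, to 0.18 ± 0.07 and accB (bll4291), of acetyl-CoA carboxylase, to 0.12 ± 0.07. For phosphate and nitrogen starvation 9 of 37 genes were higher and 3 lower, a share near that of all genes, with 12 adjusted over the list alone. The genes ntrY (blr4489), a nitrogen sensor kinase, ureF (blr1459), a urease accessory protein, and amtB rose to 0.30 ± 0.16, 0.21 ± 0.08 and 0.16 ± 0.05. Hydrogenase genes had 5 higher and 10 lower of 35 (8 and 7 with arrays centred on their median), 18 adjusted over the list alone. Of these hupI (bsl6935) rose to 0.16 ± 0.09 and hupN (bll6910) fell to −0.14 ± 0.12. Of 12 lipopolysaccharide genes 2 were lower, 2 adjusted over the list alone, and lpxA alone passed in both tests.

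The symbiosis lists had more lower than higher genes at 72 h over 18 arrays, with small changes, 0 genes over pair means and nearly even counts once arrays were centred and scaled. Of 33 nodulation genes, 1 was higher and 9 lower (2 and 6 with arrays centred on their median, 2 and 3 with arrays also scaled), 12 adjusted over the list alone. Examples are nolA (bll2019) at −0.08 ± 0.03 (adjusted p = 0.0034 and 0.075) and nodI (blr2030) at −0.08 ± 0.02 (adjusted p = 0.006 and 0.082). Of 22 nitrogen fixation genes 1 was higher and 6 lower (2 and 4 centred, 3 and 4 also scaled), 8 adjusted over the list alone. Of 10 type III secretion genes 0 were higher and 3 lower (1 and 2 centred, 1 and 1 also scaled), 4 adjusted over the list alone. The called shares of these 3 lists were near the 31.5% of all genes. The median of all genes at 72 h was −0.02, and none of these 3 lists passed camera. Among the 32 choices of sign for the 6 arrays, the real one included, as many camera calls as observed came in 14 of 32 at 4 h (1 list observed), 23 of 32 at 24 h (2 lists) and 4 of 32 at 72 h (3 lists).

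In all, 2608 genes (31.5%) were called at 72 h over 18 arrays, 1172 higher and 1436 lower, and 485 over pair means, 347 higher and 138 lower. Centring each array on its median turned the balance, to 1362 higher (61.5%) and 852 lower. The count was 1722 without array 1, 1707 without array 5 and 1008 without arrays 5 and 6, and 102 genes reached 2-fold in base 10, 92 of them higher.

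**Figure D3:**
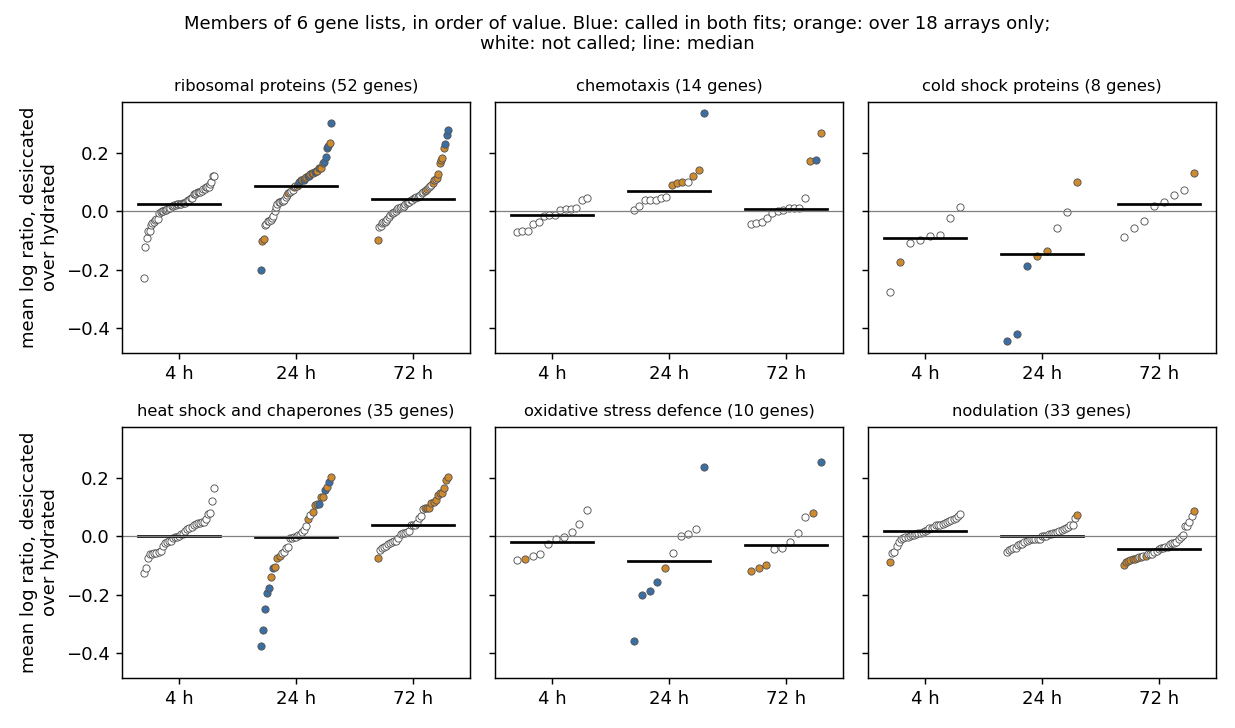
Mean log ratio, desiccated over hydrated, of each member of 6 gene lists at 4, 24 and 72 h, in order of value (blue, called in both tests; orange, over 18 arrays only; white, not called), with the list median as a line. At 24 h, 27 of 52 ribosomal protein genes were called higher and 5 of 8 cold shock genes lower.

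The response itself differed between times for a few genes in both tests. From 4 h to 24 h the change in rocD was −0.45 ± 0.05 (SE; adjusted p = 8.04e-05 and 0.0207). That in accD was −0.37 ± 0.05 (adjusted p = 0.000504 and 0.0207), and that in atpD was 0.32 ± 0.04 (adjusted p = 0.000127 and 0.0465). From 4 h to 72 h atpD differed by 0.44 ± 0.04 (adjusted p = 4.92e-06 and 0.019) and soxY by 0.33 ± 0.03 (adjusted p = 2.6e-06 and 0.019). Other large differences passed over 18 arrays only. Between 24 h and 4 h panD differed by 0.40 ± 0.08 (adjusted p = 0.0098 and 0.15). Between 72 h and 24 h glnK differed by −0.40 ± 0.08 (0.0052 and 0.17) and the cold shock gene cspA (bsl1445) by 0.36 ± 0.06 (0.002 and 0.14). The numbers of genes were 384 for 24 h against 4 h (171 higher, 213 lower; 20 over pair means), and 1552 for 72 h against 4 h (666 and 886; 5 over pair means). Regrouping the arrays as 24 h arrays 1 and 2 with 4 h arrays 1 to 4, against the rest, gave 1035 genes, more than the 384 of the real times. For 72 h against 24 h 1234 genes were called (672 and 562), and 0 over pair means by limma, where 1403 had an unadjusted p under 0.05. With arrays centred on their median, 72 h against 24 h gave 756 higher and 416 lower, and 72 h against 4 h gave 862 and 587. For 24 h against 4 h, arrays centred gave 194 higher and 191 lower, and arrays also scaled 187 and 133. The balance also turned without 24 h array 1 (262 and 196) or array 2 (252 and 210), and for 72 h against 24 h without 72 h array 2 (755 and 865) or with array weights (993 and 1061).

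Single arrays moved these counts as well. For 24 h against 4 h the count was 213, 196, 246 and 248 without 4 h arrays 3, 4, 5 and 6, and 208 and 174 without 24 h arrays 3 and 4. For 72 h against 24 h it was 756 and 813 without 24 h arrays 1 and 4, and 739 and 695 without 72 h arrays 1 and 5. For 72 h against 4 h it was 989, 962 and 938 without 4 h arrays 1, 3 and 4, and 942, 888 and 1014 without 72 h arrays 1, 5 and 6.

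Higher genes were shared between 24 h and 72 h more than lower ones. Over 18 arrays 589 genes were higher at both times, where independent lists would share 163.3, and 258 were lower at both, where independent lists would share 223.5; 67 went opposite ways. Over pair means 141 were higher at both (17.2 for independent lists) and 28 lower at both (9.4). At all 3 times 59 genes were higher and 15 lower over 18 arrays (1.98 and 3.76 for independent lists), and 68 and 8 with arrays centred on their median. The overlaps of lower genes given here rest on the 72 h list, which fell from 1436 to 852 genes with centring. All lists come from one fit that shares each gene's spread, so the numbers for independent lists are only a rough guide. Of lower genes, 16 were shared by 4 h and 72 h, fewer than the 24.1 of independent lists. Among the genes called at all 3 times otsA, rpoN2, rhlE, aglA and glgA were higher and msrA (blr0834) was lower. Over pair means, where 4 h had no calls, the number was 0. Across genes, which are not independent replicates, mean changes correlated with r = 0.65 between 4 h and 24 h, 0.54 between 24 h and 72 h and 0.22 between 4 h and 72 h. The last was 0.016 by rank. The 24 h arrays differed among themselves in this. Arrays 1 and 2 correlated with the 4 h arrays at means of 0.57 and 0.54, arrays 3 and 4 at 0.35 and 0.36, and arrays 5 and 6 at 0.11 and 0.10. With the 72 h arrays the order was the reverse, at 0.20 and 0.23, 0.40 and 0.40, and 0.45 and 0.47.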

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

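Of the tests in this part, those of a correlation between partner arrays, of other pairings at 4 h and 72 h, of splits between times that keep partners together and of the arrays that stood apart were chosen only after their results were seen.

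The response to drying differed between 24 h and 4 h, over 18 arrays, for 384 genes. The genes with a symbol that differed most upwards were panD (0.404), glnK (0.382), cheY (blr2194; 0.379), atpD (0.322) and bioB (blr2095; 0.302). Those that differed most downwards were rocD (−0.446), cisZ (bll0182; −0.404), accD (−0.374), metX (−0.349) and cvpA (−0.327). Of these 10, atpD, rocD and accD differed over pair means as well, with adjusted p values of 0.0465, 0.0207 and 0.0207; for the others they ran from 0.0854 to 0.359.

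Between 72 h and 24 h, 1234 genes differed over 18 arrays and 0 over pair means by limma (1403 at an unadjusted p under 0.05). Upward differences were those of grlA (bll5711; 0.376), ihfA (bll5019; 0.370), cspA (bsl1445; 0.362), the chaperone gene dnaK (blr0678; 0.359) and metX (0.358). Downward ones were those of glnK (−0.404), the nitrite reductase gene nirK (blr7089; −0.305), ilvC (bll6497; −0.292), fixQ (−0.218) and fixO (blr2764; −0.209). Adjusted p values over pair means lay from 0.107 to 0.286.

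Between 72 h and 4 h, 1552 genes differed over 18 arrays and 5 over pair means. The pilus genes ctpA (bsl7141; 0.636) and ctpA (bsl1442; 0.556) differed most, followed by traG (bll0043; 0.468), the ribosomal gene rpsU (bsr7117; 0.442) and fabI (blr3459; 0.439). Downward differences were smaller, for phnG (−0.252), ptmB (blr5996; −0.237), lysA (−0.203), amaB (blr3323; −0.187) and leuB (bll6321; −0.187). Over pair means these 10 had adjusted p values from 0.158 to 0.189.

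One array lay far from the other 5 of its time, by Dixon's ratio of gap to range, in 13 of 206 groups of 6 values, where chance gives about 1 in 20. At 4 h, the SD over genes of array 1 was 0.128, against 0.0543 to 0.0814 on the others. At 24 h, array 4 gave −0.323 for rpoH1 (blr5231), a heat shock sigma factor, and −0.327 for phbB (bll0225), of polyhydroxybutyrate synthesis, and array 6 gave −0.215 for irr (bll0768). At 72 h, array 2 gave −0.0582 for leuB (bll6321), 0.279 for bll5191, 0.0662 for rpmJ (bsl7548), 0.107 for hupN (bll6910) and 0.205 for hupD (bll6939). It also gave 0.00597 for fixA (blr2038), −0.201 for coxO (bll3783) and 0.0239 for fumC (blr6519), and array 4 gave −0.0669 for ntrB (blr4487). The fall of hupN and fumC at 72 h was thus measured on 5 of 6 arrays, with 0.107 and 0.0239 on array 2. This array had a mean correlation across genes of 0.29 with the 72 h arrays of other pairs, the lowest of that time.

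Counts of genes were set against other splits of the arrays, made by turning the sign of some arrays of a time (32 splits, the real one included) or by regrouping the 12 arrays of 2 times (100 splits drawn). If all arrays are independent, chance can be excluded for the 3 times: 1 of 32 splits reached 239 genes at 4 h (highest other 4), 1 of 32 reached 2439 at 24 h (highest other 1560, with array 5 turned) and 1 of 32 reached 2608 at 72 h (highest other 1281, with array 2 turned). If partner arrays share RNA, only 3 other splits keep partners together, too few for a share under 0.05. The highest of these gave 4, 1180 and 14 genes. Residuals of partner arrays correlated with 0.545, which goes against independent arrays, so chance is not excluded here. For differences between times, chance could be excluded only on the same assumption of independent arrays, which that correlation goes against. For 24 h against 4 h 2 of 100 splits reached 384, the other with 404 genes; it grouped 24 h arrays 1 to 4 with 4 h arrays 1 and 4, which points to a structure of the arrays beyond time. For 72 h against 24 h 1 of 100 splits reached 1234 (highest other 976, grouping 24 h arrays 1 to 4 with 72 h arrays 2 and 3), and for 72 h against 4 h 1 of 100 reached 1552 (highest other 0). Only 10 groupings keep partners together, too few for a share under 0.05. The highest other of these gave 1035 genes against the real 384 for 24 h against 4 h, grouping 24 h arrays 1 and 2 with 4 h arrays 1 to 4, so a structure of the arrays other than time parts these 12 arrays further than time does. For 72 h against 24 h it gave 1030 against 1234, and for 72 h against 4 h 6 against 1552. For the gene list tests chance cannot be excluded: 14 of 32 splits gave as many as the 1 list at 4 h (highest other 2), 23 of 32 as many as the 2 lists at 24 h (highest other 4) and 4 of 32 as many as the 3 lists at 72 h (highest other 3).

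Fewer genes passed when presumed partner arrays were averaged: 0 against 239 at 4 h (limma; 794 at an unadjusted p under 0.05), 974 against 2439 at 24 h and 485 against 2608 at 72 h. Fewer values alone are argued against at 24 h and 72 h, where averaging in the other 5 pairings of opposite dye gave 1807 to 2780 and 1535 to 3056 genes. At 4 h the other pairings gave 2 to 952, so fewer values alone at 4 h stay open. Shared RNA within a pair is consistent with a correlation of 0.545 between the residuals of partner arrays. An effect of shared labelling or scanning days stays open, since the labels give none, and no biological explanation was tested.

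At 4 h arrays 5 and 6, and at 24 h arrays 1 and 2, stood apart from their times: the former correlated with 4 h arrays 1 to 4 at a mean of 0.192, the latter with 24 h arrays 3 to 6 at 0.375 but with 4 h arrays 1 to 4 at 0.672. At 24 h arrays 5 and 6 fitted their time no better (0.371 and 0.329 with the other pairs) and were nearer to the 72 h arrays, at a mean of 0.461 against 0.217 for arrays 1 and 2. A swap between these arrays is argued against, since 4 h arrays 5 and 6 correlated with 24 h arrays 3 to 6 at a mean of 0.102, below the 0.329 that was lowest among 24 h arrays. Noise separate on each of 4 h arrays 5 and 6, as all that they measured, is argued against by their correlation with each other of 0.571. Noise or a weak response in RNA that both arrays share would leave that correlation in place, so the value cannot decide on it. The SDs over genes of arrays 5 and 6, 0.0632 and 0.0543, were the lowest at 4 h. Whether 24 h arrays 1 and 2 held RNA of 4 h could not be decided: their mean SD over genes, 0.154, lay above the 4 h range of 0.0543 to 0.128, but not by more than 2 SD of the 4 h values. A response that ran at a different pace in the cells behind each pair at 24 h may also have placed arrays 1 and 2 near 4 h and arrays 5 and 6 near 72 h; this biological explanation was not tested, and it stays open.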

How the results depend on the processing

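The plain-tag probe, leaving out 2 partner arrays together, pair means without 4 h arrays 5 and 6, and pairs in the overlap of times were chosen only after results were seen. Of 230 results for named genes, 0 reversed under the alternatives of the next 2 sentences, which says little. Without the dye term, with times fitted alone, robust eBayes, the replicate block, either use of pairs or a 2-fold minimum, the means stay the same in this balanced design. No result could reverse there. Genes named for a time by the rule had the same sign on 6 of 6 arrays, so leaving out 1 array could hardly reverse them. Calls were lost for 0 with no dye term, 1 each with array weights, robust eBayes and the replicate block, 3 with the plain-tag probe, 8 with arrays centred, 11 with arrays also scaled, 37 with times fitted alone, 59 with pairs as a random block, 118 with pairs averaged (24 of 24 at 4 h, 21 of 89 at 24 h, 46 of 87 at 72 h and 27 of 30 differences) and 153 with a 2-fold minimum. Leaving out some one array ended 48, 22 of 24 of them at 4 h. With the plain-tag probe flaA (blr3695) stood at 0.041 at 4 h (adjusted p = 0.24 by limma), and at 0.12 with its probes averaged (adjusted p = 0.046). Only genes with several probes, 192 of 8268, could change values there, so the 3 lost calls say little about how probes of a gene differ. Signal over background was not used here, so what weak spots limit is unknown, and the filter to genes on all 18 arrays removed none.

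Counts of genes stayed within 1.5 times with arrays centred, robust eBayes and the plain-tag probe for the 3 times and 3 differences. The plain-tag probe could change the values of at most 192 of 8268 genes, so its counts had little room to move. For counts that moved, the cause was not tested except where a reason is given. With no dye term the 4 h count was 393, and 119 genes in place of 74 were called one way at all 3 times. With arrays centred and scaled 4 h gave 1584, and 72 h against 24 h gave 790. With times fitted alone 4 h gave 1000, 24 h 891 and 72 h against 24 h 421, so 4 h then had more genes than 24 h. With array weights 4 h gave 4928, where arrays 3 and 4 were weighted 8.9 and 8.1, 72 h gave 4077, and the differences gave 1955 (24 h against 4 h), 2054 (72 h against 24 h) and 4482 (72 h against 4 h). With the replicate block, whose numbers are not shown to pair arrays across times, 4 h gave 615.

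With presumed pairs averaged the counts were 0 at 4 h (limma, with 794 at an unadjusted p under 0.05), 974 at 24 h and 485 at 72 h. They were 20 for 24 h against 4 h, 0 for 72 h against 24 h (1403 unadjusted), 5 for 72 h against 4 h, and 0 at all 3 times. Averaging leaves fewer values, but that alone is argued against as the cause at 24 h and 72 h, as given above. Without 4 h arrays 5 and 6 the averaged pairs still gave 0 at 4 h (1086 unadjusted). With pairs as a random block the counts were 4, 1606 and 1107 at 4, 24 and 72 h, 80, 264 and 171 for the differences in the same order, and 3 at all 3 times. With a 2-fold minimum in base 10 they were 10, 211 and 102, then 64, 75 and 74, and 5 at all 3 times.

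With one array left out, counts ran from 6 to 428 at 4 h, 1872 to 2596 at 24 h, 1707 to 2679 at 72 h, 174 to 489 for 24 h against 4 h, 695 to 1802 for 72 h against 24 h and 888 to 2054 for 72 h against 4 h. Partner arrays left out together gave at 4 h 0 without arrays 1 and 2 (607 unadjusted), 11 without 3 and 4 and 710 without 5 and 6. At 24 h the count was 1354 without arrays 3 and 4, and at 72 h 1008 without 5 and 6. Arrays with desiccated cells in cy3, 3 per time, gave 0 at 4 h (1336 unadjusted), 740 at 24 h and 995 at 72 h. Those in cy5 gave 0 (345 unadjusted), 708 and 138.

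Responses at 24 h and 72 h correlated at 0.37 by rank. Those at 4 h and 72 h correlated at 0.016 by rank, and at 0.32 over genes called at either time. Of 96 gene list tests, camera with an estimated correlation called 0 (10 at an unadjusted p under 0.05) and fry 40, which asks another question; camera on arrays centred and on pair means called 6 each. On pair means fry called 7: protease, sigma factor, DNA repair, ATP synthase and iron genes at 24 h, and sigma factor and lipopolysaccharide genes at 72 h.

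Whether more genes were higher or lower depended on the setting too. At 4 h (100 higher, 139 lower) the balance turned to 502 and 498 with times fitted alone, 2686 and 2242 with array weights, 4 and 0 with pairs as a random block, 10 and 0 at 2-fold, 5 and 1, 12 and 3, and 11 and 5 without arrays 1, 2 and 4, and 7 and 4 without arrays 3 and 4. At 24 h (1152, 1287) it turned with arrays centred (1247, 1202) or also scaled (1076, 1004) and without arrays 1 and 2 (952, 912). At 72 h (1172, 1436) it turned in more settings, among them arrays centred (1362, 852), times alone (988, 768), pairs averaged (347, 138) or as a random block (725, 382), and without array 1 (935, 787), 5 (900, 807) or 6 (931, 863). For 24 h against 4 h (171, 213) it turned with arrays centred (194, 191) or also scaled (187, 133) and without 24 h array 1 (262, 196) or 2 (252, 210). The balance for 72 h against 24 h (672, 562) turned with array weights (993, 1061) and without 72 h array 2 (755, 865). That for 72 h against 4 h (666, 886) turned with arrays centred (862, 587) or also scaled (1208, 977), pairs averaged (5, 0) or as a random block (131, 40), and at 2-fold (68, 6).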

Other observations

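Among the tests in this part, the permutation test of neighbouring genes was chosen only after the correlations were seen.

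At 72 h, a time at which they are not described above, further gene groups had members that passed; these were fixed beforehand but picked for 72 h after their values were seen, with adjusted p values again over 18 arrays and over pair means. Over all genes 31.5% were called at 72 h over 18 arrays, a share that the flagellar list below was near. Of 10 genes for oxidative stress defence, 2 were higher and 3 lower (3 and 2 with arrays centred and scaled), 5 adjusted over the list alone. The superoxide dismutase gene sodF (bll7774) was still higher, at 0.25 ± 0.07 (SD, n = 6; adjusted p = 1.4e-06 and 0.004), and msrA (blr0834) stood at −0.10 ± 0.03 (adjusted p = 0.0013 and 0.06). Of 29 DNA repair genes 4 were higher and 2 lower, 6 adjusted over the list alone. The recombination gene recR (bll8114) rose to 0.20 ± 0.09, and recA (bll5755) stood at 0.13 ± 0.05 (adjusted p = 0.0033 and 0.08). Cytochromes and their oxidases had 6 higher and 7 lower of 34 (6 and 4 with arrays centred, 5 and 5 also scaled), 13 adjusted over the list alone. Of these cycA (blr7544) and the cytochrome c maturation genes ccmG (blr0471) and ccmD (bsr0470) rose to 0.19 ± 0.07, 0.28 ± 0.09 and 0.16 ± 0.11. Flagellar genes had 9 higher and 8 lower of 55 (10 and 5 with arrays centred), 17 adjusted over the list alone, and bll5845 and bll5846 rose to 0.36 ± 0.15 and 0.35 ± 0.12. In these 4 lists camera pointed upwards while the median lay below 0, and 0 of the 4 passed it. The mean lay below 0 for oxidative stress and cytochrome genes, and the median of the DNA repair and flagellar lists lay above 0 with arrays centred.

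Of 17 genes of the TCA cycle, 1 was higher and 3 lower at 72 h, 3 adjusted over the list alone, and the fumarase gene fumC (blr6519) fell to −0.12 ± 0.08 (adjusted p = 0.0014 and 0.045). Of 3 genes of glycerol use, glycerol being in the growth medium, 1 was higher, adjusted over the list alone as well: glpD (bll7106), glycerol-3-phosphate dehydrogenase, at 0.18 ± 0.12 (adjusted p = 0.00077 and 0.046). Exopolysaccharide genes had 3 higher and 0 lower of 10, 3 adjusted over the list alone, and exoM (bll7574) rose to 0.20 ± 0.08. Of 6 genes for compatible solutes and osmolyte transport, 0 were called at 4, 24 or 72 h over all genes by limma, and 1, 0 and 0 adjusted over the list alone. With arrays centred 1 was higher at 24 h, and with arrays also scaled 2 were higher at 4 h.

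Genes that are neighbours by locus tag number responded alike, more so on one strand. At 24 h the changes of consecutive genes correlated across genes with r = 0.275 over 5531 pairs on one strand and 0.136 over 2690 pairs on opposite strands, a difference of 0.139, which suggests, as a hypothesis, transcription of neighbours in one unit. Shared position on the array as the whole cause is argued against by a permutation p of 0.00121 for that difference, taken as mean products of standardised changes (adjusted 0.00306; 100000 permutations of pairs between the strand classes, 2-sided). As a part of the cause it stays open, with the 0.136 on opposite strands. The differences at 4 h and 72 h were 0.114 (permutation p = 0.00719, adjusted 0.00719) and 0.127 (permutation p = 0.00204, adjusted 0.00306). Where both neighbours were called over 18 arrays at 24 h, they went the same way in 462 of 594 pairs on one strand (77.8%) and 183 of 308 on opposite strands (59.4%), and at 72 h in 448 of 601 (74.5%) and 177 of 276 (64.1%). Pairs that share a gene are not independent, and tag numbers stand in for positions, which were not matched. Different probes of one gene correlated at only 0.17 at 24 h over 212 probe pairs, below the 0.275 of neighbours on one strand. The hypothesis of one unit thus rests on values in which even probes of one gene agreed little. Runs of at least 4 consecutive genes called one way in both tests were blr0209 to blr0212, from the competence gene comF on, bll5478 to bll5481 and bll5940 to bll5943, lower at 24 h, and bll1463 to bll1467, higher at 72 h by 0.16 to 0.47.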
